A study of Mus musculus with 4 samples.

How the data were processed

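Poly(A)-enriched RNA was sequenced from myeloid cells sorted from mouse livers, in 2 libraries of LysM-Cre IL10R fl/fl and 2 of LysM-Cre IL10R wt/wt. Per the labels' protocols, livers were perfused and digested with DNase and collagenase, immune cells were enriched on Percoll and sorted, and RNA was taken up in Trizol. The authors deposited one table of raw counts per Ensembl gene for all 4 libraries, with 55487 genes. The values are whole numbers, and the column totals are 22694136, 26441014, 17750343 and 17154042. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.33 and STAR 2.5.0 were used on the GRCm38 build. The counting tool, its strand setting and the annotation release are not given in the sources used here. Symbols, positions and exonic overlaps came from GENCODE release M21 (GRCm38), which held 55141 of the identifiers; 346 were without a symbol.

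The genotypes were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group and a minimum count of 10, which left 13496 of 22696 genes with any count, TMM scaling, and the quasi-likelihood F test without covariates. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 is called passing. Fold changes are fl/fl over wt/wt with a prior count of 0.125, the SE is the absolute log2 fold change over the square root of F, and CPM are TMM-scaled. With 2 libraries against 2, the smallest p of an exact permutation test is 0.333, so that such a test cannot pass. The biological coefficient of variation was 25.5%. The same steps were tested on simulated data of 13496 genes. There 56%, 100%, 100% and 100% of 50 genes were recovered at log2 changes of 1, 2, 3 and 4. Calls among 12880 unchanged genes numbered 7. The changed genes had at least median expression, and each gene's spread was set to the dispersion trend, without gene-wise deviations from it. Recovery in the data can be lower: Il1a at a log2 fold change of −2.80 and Chil3 at 2.33 did not pass. Depth limits the floor of a library to 3 counts where a gene has 0, which covers counting error only, since PCR copies cannot be told from separate molecules.

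The comparison, the test, the named genes, 21 functional lists, 19 lists of cell type markers and the alternative settings, except those said to be added, were chosen before the data were examined. The 40 lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01 against all other tested genes, on log-CPM with a prior count of 2, with adjustment over the 40 lists. With the correlation estimated from the data, 0 of the 18 lists past the threshold kept their call, and fry called 0 lists. Fry asks whether a list's genes move one way on balance. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom, so it has little power with 4 libraries. The estimated correlation was below the preset 0.01 for oxidative phosphorylation (0.00468), lysosome and lipid handling (−0.0410) and alternative activation (−0.0182). For these lists, the lost call therefore does not show that correlation between genes had produced it. The estimate was far above 0.01 for others, such as cell cycle (0.883), granulocyte precursor (0.836), glycolysis and hypoxia (0.765) and type I interferon genes (0.742). For such lists the p-values at the preset correlation can be too small, and correlation as a source of the call stays open. Some genes are in more than 1 list: C1qa, C1qb and C1qc, S100a8 and S100a9, Vegfa, Msr1, Egr2 and Hmox1 among them. Genes were named by this rule: Il10ra, Il10rb, Il10, Stat3, Socs3, Cd274, Pdcd1lg2 and Lyz2 always; the 10 higher and 10 lower genes with the largest absolute log2 fold change among those past the threshold with a symbol, at least median expression and separated libraries; and in each list described, up to 4 members with the smallest unadjusted p, with the 2 most expressed members for lists of another cell type. A gene outside the rule is said to have been named after its values were seen. Results of some genes that the rule names are not reported here.

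Alternatives were RLE size factors, library size only and upper quartile scaling, no filter, a filter at CPM of at least 5, a prior count of 5, DESeq2 1.42.0, limma-voom, the replicate number as a block, a test against a fold change of 1.5, and leaving out each library. With a library left out, its group has 1 library, which is assumed to vary like the other group. Without a fl/fl library the spread comes from the wt/wt pair alone. That pair was closer, at an SD of log2 differences of 0.631 against 0.814 within fl/fl. Calls in those fits therefore do not measure the spread within fl/fl. Added after the data were seen were DESeq2 on 3 libraries, list medians without a trend on gene length, the neutrophil factor list without members of the fixed lists, and 6 lists: TGF-beta signalling, growth and angiogenic factors, integrins and adhesion receptors, neutrophil transcription factors and granule genes, cytosolic ribosomal proteins and mitochondrially encoded genes. No library was left out of the analysis, and no sex term was fitted, since the only library with Xist counts is in the fl/fl group with 1 other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.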

Results

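Gene expression was measured in myeloid cells sorted from mouse livers of 2 genotypes that differ in the interleukin-10 (IL-10) receptor gene. LysM-Cre places the Cre recombinase under the lysozyme 2 locus, which is active in macrophages, monocytes and granulocytes, and Cre removes the DNA between the loxP sites of a floxed (fl) gene. The groups were LysM-Cre with a floxed receptor gene (fl/fl, n = 2) and LysM-Cre with an unmodified one (wt/wt, n = 2). The sort kept cells with CD45 and CD11b on the surface and without CD3 and CD11c, a gate that can hold monocytes, macrophages and granulocytes. Total counts were 22694136 and 26441014 in wt/wt libraries 1 and 2, and 17750343 and 17154042 in fl/fl libraries 1 and 2. Xist, the RNA of X inactivation, had 4298 counts in fl/fl 2 and 0 in the other libraries, and 4 Y-linked genes together had 1 count in fl/fl 2 against 5207, 6562 and 3455 in wt/wt 1, wt/wt 2 and fl/fl 1. A count of 0 allows up to 3 counts, which is 0.135, 0.111 and 0.175 CPM (library-scaled counts, with TMM factors) in those libraries. The labels do not give the sex of the mice, whether the livers held tumours, or whether the libraries of a group came from separate animals. The p-values here therefore measure the spread between these samples. By the Xist and Y-linked counts, fl/fl 2 was female and the other libraries were male. The fl/fl libraries thus came from different mice, and that group mixed the sexes.

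Across 13496 tested genes, the Pearson correlation of log values was 0.975 between the wt/wt libraries and 0.960 between the fl/fl libraries, against 0.921 to 0.941 between genotypes; genes are not independent replicates. The first principal component held 62.5% of the variance and separated the genotypes. The second component held 23.9% and separated fl/fl 1 from fl/fl 2, at 44.6 and −49.1, so the fl/fl libraries differed from each other in a large set of genes.

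The design compares fl/fl with wt/wt to ask what liver myeloid cells express when LysM-Cre acts on the IL-10 receptor gene, and the series title names PD-L1. Il10ra (ENSMUSG00000032089; GRCm38 chromosome 9, 45253837 to 45269149, minus strand) encodes the ligand-binding chain of the receptor; the labels write IL10R without naming the chain, and Il10ra was taken as the floxed gene before the data were examined. Its level was 1052 ± 83.0 CPM (SD, n = 2) in wt/wt and 42.1 ± 38.5 CPM (SD, n = 2) in fl/fl, so that Il10ra was 25.0-fold lower in fl/fl. The fl/fl libraries held 69.3 and 14.8 CPM of Il10ra, from 1190 and 260 counts, against 24730 and 26968 counts in wt/wt. The log2 fold change was −4.64 ± 0.68 (SE; adjusted p = 0.0193 by the edgeR quasi-likelihood test). The Il10ra log2 fold change was −6.18 without fl/fl 1 and −3.92 without fl/fl 2, and its adjusted p was 0.159 without wt/wt 1 and 0.0905 without wt/wt 2, in a range of 7.21e-90 to 0.159 over all alternatives. Gene totals do not separate reads of a deleted part of a gene from reads of the remaining exons.

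Other parts of the IL-10 pathway differed less. Il10rb, the shared second chain, held 96.2 and 90.4 CPM in wt/wt and 64.9 and 61.7 in fl/fl (log2 fold change −0.56, adjusted p = 0.0854, edgeR). Stat3, the transcription factor that carries the IL-10 signal, held 338 and 313 CPM in wt/wt and 346 and 324 in fl/fl, and Socs3, its feedback inhibitor, held 1423 and 1042 against 1246 and 1136 CPM. Il10 itself was at 10.3 and 4.05 CPM in wt/wt and 4.19 and 1.48 in fl/fl (adjusted p = 0.277; log2 fold change from −2.30 to −0.56 with single libraries left out). Socs1, a second feedback inhibitor, had a log2 fold change of −0.93 (adjusted p = 0.162; −1.31 to −0.47). Of the 11 tested genes of IL-10 receptor and JAK-STAT3 signalling, Il10ra was lower and the other 10 did not pass (0 higher and 2 lower when adjusted over the list alone). Of 16 genes that IL-10 is known to induce in macrophages, 2 fell in fl/fl: Il21r, an interleukin-21 receptor chain (log2 fold change −1.98, adjusted p = 0.0215), and Hmox1, the heme-degrading enzyme (−0.85, adjusted p = 0.0306). Adjusted over the list alone, 1 was higher and 4 lower, and without fl/fl 1 or fl/fl 2 the number lower over all genes was 4 or 5, with 1 higher without fl/fl 2. Ddit4 and the decoy receptor gene Il1r2 of this list were at log2 fold changes of −1.36 and 1.74 (adjusted p = 0.0865 and 0.115), at −2.12 and 0.45 without fl/fl 1 and at −0.87 and 2.41 without fl/fl 2. Neither list passed camera, at adjusted p = 0.242 and 0.0853. Granulocyte markers differed in the same libraries, with medians of 3.45 for precursor and 1.66 for mature neutrophil genes. Lyz2, the locus that carries Cre, held 18.4 and 23.3 CPM in wt/wt and 26.4 and 80.4 in fl/fl (adjusted p = 0.152, edgeR). Its log2 fold change was 1.36, or 1.91 without fl/fl 1 and 0.34 without fl/fl 2. The near-identical neighbour Lyz1 held 566, 473, 283 and 161 CPM.

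Cd274 (ENSMUSG00000016496; chromosome 19, 29367455 to 29388095, plus strand), the gene of PD-L1, which restrains T cells through PD-1, held 58.2 ± 19.3 CPM (SD, n = 2) in wt/wt and 39.6 ± 8.81 CPM (SD, n = 2) in fl/fl. The libraries overlapped, at 71.8 and 44.5 CPM in wt/wt and 33.4 and 45.8 in fl/fl. The Cd274 log2 fold change was −0.55 ± 0.27 (SE; adjusted p = 0.296, edgeR), from −0.86 to −0.22 when single libraries were left out, and no alternative put it past the threshold; 14.1% of its exonic length is shared with a gene on the opposite strand. In simulated data of this design, 56% of genes with a log2 change of 1 and at least median expression were recovered. Smaller changes such as the value of Cd274 were not simulated. Pdcd1lg2, the gene of PD-L2, held 0.584 and 0.626 CPM in wt/wt and 0.0582 and 1.94 in fl/fl (adjusted p = 0.798). Among 17 tested checkpoint ligands and receptors, 4 fell and 13 did not pass. These were Cd276, the gene of B7-H3 (log2 fold change −3.06), Havcr2, the gene of TIM-3 (−2.23), Pvr, a ligand of TIGIT (−1.40), and Icosl, the ligand of ICOS (−1.10). Adjusted over the list alone, 7 were lower. The median log2 fold change of the list was −0.60, and from −0.86 to −0.21 with single libraries left out. The checkpoint list passed camera with a preset correlation (adjusted p = 0.00274) but not with the correlation estimated (adjusted p = 0.595 with an estimated correlation). Granulocyte precursor and neutrophil lists had medians of 3.45 and 1.66 in these libraries.

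**Figure D1:**
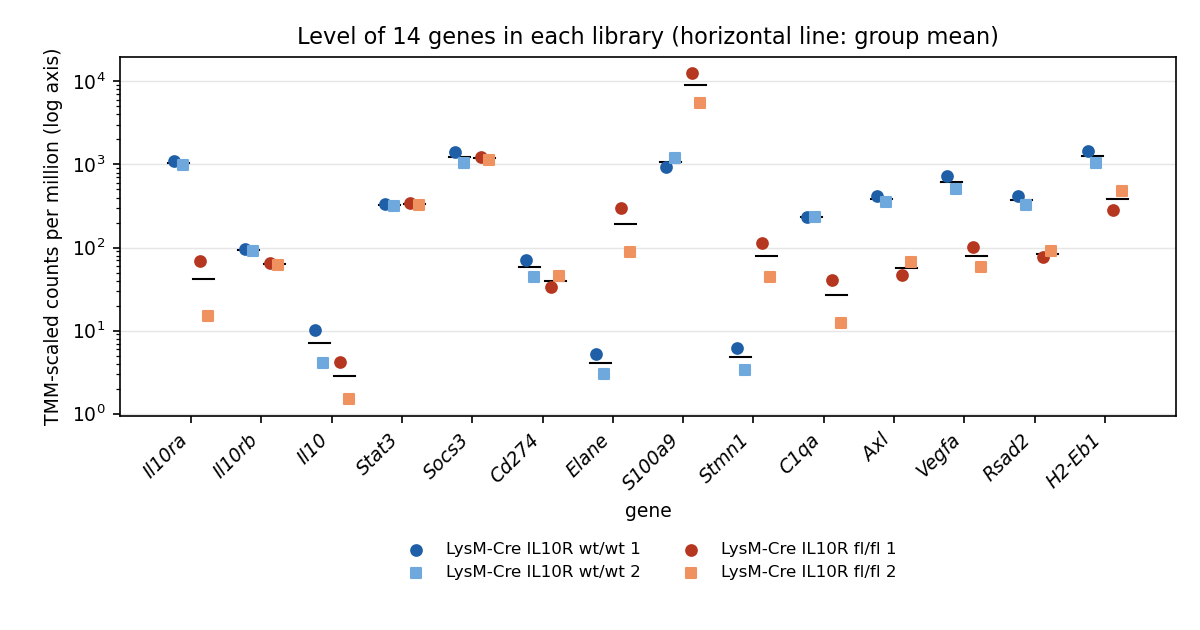
TMM-scaled CPM, on a log axis, of 14 genes in each library: blue for wt/wt and red or orange for fl/fl, circles for replicate 1, squares for replicate 2, and lines for the group means. Il10ra lay at 1111 and 993 CPM in wt/wt and at 69.3 and 14.8 in fl/fl, whereas the Cd274 values of the genotypes overlapped.

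Across all genes, 790 of 13496 differed between the genotypes by the edgeR quasi-likelihood test, 363 higher and 427 lower in fl/fl, and 671 of them by at least 2-fold. All 790 had both libraries of a genotype above both of the other, as did 54.4% of all tested genes, where chance gives 33.3%. Among the 10 leading genes higher in fl/fl, besides Mpo and Elane, were Ggt1, a glutathione-degrading enzyme (log2 fold change 7.57), Prok2, a secreted factor made by neutrophils (6.91), Lipg, a lipase (6.88), the acute-phase gene Saa3 (5.98), the precursor gene Ms4a3 (5.15), Cmah, an enzyme of sialic acid synthesis (4.43), Wfdc21 (4.39) and the metalloreductase Steap4 (4.23). Limma-voom did not call Ggt1, Prok2, Lipg or Ms4a3. Saa3 held 1208 and 164 CPM in fl/fl 1 and 2 against 10.3 and 11.4 in wt/wt (log2 fold change 3.88 without fl/fl 1 and 6.81 without fl/fl 2), whereas Steap4 held 69.5 and 76.6 against 2.56 and 5.16. Ggt1, with 0 and 11 counts in wt/wt 1 and 2, was at 5.07 without fl/fl 1, and without wt/wt 2 its value rests on the prior count. Prok2 was at 4.30 without fl/fl 1, and Lipg at 4.83 without fl/fl 1. The leading genes lower in fl/fl, besides Il10ra, C3ar1, C1qa and Ccl7, were Ltbp3, which binds latent TGF-beta (−4.06), the ectonucleotidase Nt5e, known as CD73 (−3.51), the transporter Abcc3 (−3.27), Rai14 (−3.15), the oxygen-sensing prolyl hydroxylase Egln3 (−3.14) and the growth factor Pdgfb (−3.13). Nt5e was at −5.28 without fl/fl 1, and C3ar1 at −5.45. Without wt/wt 1 or wt/wt 2, edgeR called 0 genes, with 1576 and 2333 genes at an unadjusted p under 0.05, while DESeq2 on the same 3 libraries called 464 and 771 genes. Without fl/fl 1 or fl/fl 2, edgeR called 977 and 1477 genes. Each edgeR call of a gene or a list member in the text depends on both wt/wt libraries in this way. With either of them left out, no list kept a called gene in edgeR. In those fits the spread comes from the fl/fl pair alone. Without wt/wt 1 and wt/wt 2, the Il10ra log2 fold change was −4.61 and −4.72, and the granulocyte precursor median 3.38 and 3.83. The calls were thus lost while these effects kept their size.

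**Figure D2:**
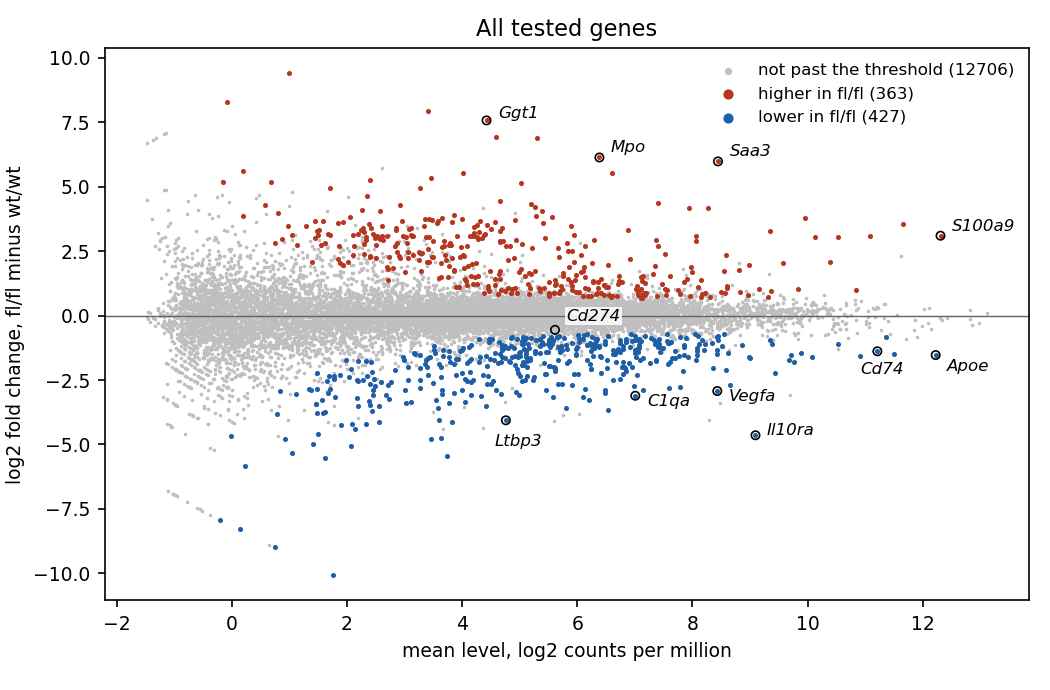
Log2 fold change of fl/fl over wt/wt against mean log2 CPM for each of 13496 tested genes, with 363 higher genes in red, 427 lower genes in blue and the others in grey. Saa3, Mpo and S100a9 lie among the higher genes and Il10ra, Ltbp3 and C1qa among the lower, Cd274 lies among the grey points, and fitted values of genes without counts in a whole group depend on the prior count.

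Granulocyte genes were higher in fl/fl. Elane and Mpo, enzymes of the primary granules made by granulocyte precursors, stood at 296 and 87.8 CPM and at 267 and 62.7 CPM in fl/fl 1 and 2, against 5.21 and 3.02 CPM and 2.56 and 2.14 CPM in wt/wt. The secondary granule genes Camp (log2 fold change 3.06 ± 0.22, SE) and Ltf (3.04 ± 0.29, SE) rose as well. S100a9, the calprotectin subunit abundant in neutrophils, held 12617 and 5566 CPM in fl/fl and 923 and 1200 in wt/wt, and Ly6g, a surface marker of neutrophils, held 108 and 48.7 CPM against 4.67 and 8.22. Of 12 tested granulocyte precursor genes, 11 rose and 1 did not pass (11 higher when adjusted over the list alone), with a median log2 fold change of 3.45. Of 18 mature neutrophil genes, 7 rose, among them S100a8 (3.54) and the stefin gene Stfa2l1 (3.41, or 2.09 without fl/fl 1; not called by limma-voom), and 11 did not pass (13 higher when adjusted over the list alone). Camera gave adjusted p = 1.40e-09 for the precursor list and 4.16e-06 for the neutrophil list, each with adjusted p = 0.595 with an estimated correlation. These genes were higher in fl/fl 1 than in fl/fl 2: the median of the precursor list was 2.69 without fl/fl 1 and 4.0 without fl/fl 2, that of the neutrophil list was 0.88 and 2.21, and 13 neutrophil genes passed without fl/fl 2. Mpo and Elane were at 4.70 and 4.39 without fl/fl 1 and at 6.84 and 6.19 without fl/fl 2.

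Cell cycle genes rose beside the granulocyte genes. Stmn1, a regulator of microtubules, held 115 and 44.2 CPM in fl/fl and 6.15 and 3.39 in wt/wt. Birc5 (survivin), Kif11, a motor of the mitotic spindle, and Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, had log2 fold changes of 3.29, 3.53 and 3.81. All 28 tested cell cycle genes had a positive log2 fold change, with a median of 2.78, and 17 of them passed (26 higher when adjusted over the list alone); DESeq2 called 22 and limma-voom 7. The camera call (adjusted p = 1.60e-11) was lost with the correlation estimated (adjusted p = 0.595 with an estimated correlation). The median was 1.74 without fl/fl 1 and 3.41 without fl/fl 2, where 27 genes passed.

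The lists of 3 further blood cell types passed camera upward, with 4, 1 and 0 members past the threshold in edgeR. Of 13 classical monocyte genes, 3 rose and 1 fell: the haptoglobin gene Hp (2.08) and Mgst1 (1.12) were among those higher, and the fibronectin gene Fn1 was lower (−1.48), while Chil3 was at 2.33 (adjusted p = 0.0865; 0.95 without fl/fl 1 and 3.02 without fl/fl 2). Adjusted over the list alone, 7 monocyte genes were higher and 1 lower, and the counts over all genes without fl/fl 2 were also 7 and 1. Of 10 basophil and mast cell genes, Hdc, the enzyme that makes histamine, rose by 1.90 (1 higher when adjusted over the list alone, and 4 over all genes without fl/fl 2). Kit, Mcpt8 and Prss34 were at 2.66, 2.09 and 3.40 without passing (0.78, 1.21 and 2.05 without fl/fl 1), and Gata2 was at 0.05. All 4 tested hemoglobin genes of the erythroid list were positive and none passed in edgeR, with 3 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom (2 higher when adjusted over the list alone, and 2 over all genes without fl/fl 1): Hba-a1 was at 1.86 (adjusted p = 0.0653), Hbb-bs at 1.53, Hbb-bt at 1.52 and Hba-a2 at 1.87. Without fl/fl 2 these 4 genes were at 0.98, 0.76, 0.78 and 0.53, and the median of the list was 0.77, against 2.37 without fl/fl 1. Each of the 3 lists had a camera adjusted p = 0.0264 and, in each case, adjusted p = 0.595 with an estimated correlation. The camera call of the monocyte list ended without wt/wt 2 (adjusted p = 0.104), and that of the basophil list without wt/wt 1 (0.128) or fl/fl 2 (0.0981).

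Some genes of macrophage functions fell in fl/fl. C1qa, a chain of the complement protein C1q, held 231 and 230 CPM in wt/wt and 41.1 and 12.3 in fl/fl, and C3ar1, the receptor for complement fragment C3a, held 192 and 152 against 22.8 and 4.05. Axl, a receptor for the uptake of dying cells, held 419 and 351 CPM in wt/wt and 46.6 and 67.1 in fl/fl (log2 fold change −2.76 ± 0.23, SE; adjusted p = 0.00879, edgeR). Of 20 phagocytosis and complement genes, 8 fell, C1qb (−2.83) and the scavenger receptor Msr1 (−1.36) among them, 1 rose and 11 did not pass (1 higher and 10 lower when adjusted over the list alone). The gene that rose was C3, the central complement component (0.72, adjusted p = 0.0484, named after its values were seen); it no longer passed without fl/fl 1 (0.0583). Of 13 Kupffer cell genes, 4 fell, which were Hmox1 and C1qa, C1qb and C1qc, also members of the other lists, and the Kupffer list did not pass camera (adjusted p = 0.0651; 4 lower when adjusted over the list alone). Adgre1, the gene of the macrophage marker F4/80, held 178 and 183 CPM in wt/wt and 150 and 156 in fl/fl, and was named after its values were seen. Of 17 alternative activation genes, 4 fell (1 higher and 7 lower when adjusted over the list alone): Mmp12 (−3.69, not called by limma-voom), Msr1, Egr2 (−1.19) and Tgfb1 (−0.94). Without fl/fl 1, 7 genes of this list were lower, and without fl/fl 2, 8 were lower and 1 higher. Of 22 lysosome and lipid genes, 3 fell, the cholesterol exporter Abca1 (−2.22), the protease Lgmn (−2.21) and the lipid carrier Apoe (−1.53), and the tetraspanin Cd63 rose (1.71, or 1.13 without fl/fl 1). Adjusted over the list alone, 1 was higher and 4 lower, and 5 and 4 were lower over all genes without fl/fl 1 and fl/fl 2. Camera gave adjusted p = 0.000102, 0.00996 and 0.0265 for the phagocytosis, alternative activation and lysosome lists, and for each of them adjusted p = 0.595 with an estimated correlation. The alternative activation call ended without fl/fl 1 (adjusted p = 0.113), and the lysosome call without wt/wt 2 (0.0818) or fl/fl 2 (0.133). Without fl/fl 1, C1qa and C3ar1 were at −4.26 and −5.45, and without fl/fl 2 at −2.48 and −2.91. Granulocyte precursor genes were higher in the same fl/fl libraries, at a median log2 fold change of 3.45.

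Some genes of antigen presentation by MHC class II fell in fl/fl. H2-Eb1, which encodes a class II beta chain, held 1459 and 1043 CPM in wt/wt and 284 and 475 in fl/fl (log2 fold change −1.72 ± 0.29, SE; adjusted p = 0.0253, edgeR). Cd74, the invariant chain, and H2-Aa, an alpha chain, fell as well (−1.39 and −1.44), and H2-Ab1 was at −1.30 (adjusted p = 0.0546; −1.0 without fl/fl 1 and −1.74 without fl/fl 2). Of 12 class II genes, 3 fell and 9 did not pass, with 10 lower when adjusted over the list alone, and 5 and 8 lower over all genes without fl/fl 1 and fl/fl 2. Camera gave adjusted p = 2.50e-05 for the class II list, and adjusted p = 0.595 with an estimated correlation. None of 20 MHC class I genes passed in edgeR, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom, and their median log2 fold change was 0.03 (mean −0.01; camera adjusted p = 0.872). The same fl/fl libraries had higher granulocyte precursor and mature neutrophil genes, at medians of 3.45 and 1.66.

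Some interferon-stimulated genes and chemokines fell too. Rsad2 (viperin), an antiviral enzyme, held 423 and 326 CPM in wt/wt and 77.2 and 92.1 in fl/fl (log2 fold change −2.15 ± 0.20, SE; adjusted p = 0.00879, edgeR). Of 30 type I interferon stimulated genes, 10 fell, with Ifit3b at −1.68, Mx1 at −1.64 and Oasl1 at −1.32, and 20 did not pass. Adjusted over the list alone, 16 were lower, and camera gave adjusted p = 8.17e-07 for the list. Its median was −0.62, or −0.54 without fl/fl 1 and −0.86 without fl/fl 2. The interferon list had adjusted p = 0.595 with an estimated correlation. Of 27 interferon-gamma response genes, Cxcl10 alone fell (−1.32, adjusted p = 0.0487, named after its values were seen; 0.0579 without fl/fl 1, and 2 genes passed without fl/fl 2), 0 passed when adjusted over the list alone, with 6 at an unadjusted p under 0.05, 5 called by DESeq2 and 1 by limma-voom, and the list did not pass camera (adjusted p = 0.133). Of 19 chemokine genes, 6 fell (8 lower when adjusted over the list alone), among them the monocyte attractants Ccl2 (−1.80), Ccl7 (−3.60) and Ccl12 (−2.90) and the CXCR6 ligand Cxcl16 (−2.46). Of 15 pro-inflammatory cytokine genes, Lif, a cytokine of the IL-6 family, fell (−2.05), and Il1a, Tnfsf10 and Csf1 were at −2.80, −1.54 and −1.13 without passing. Without fl/fl 1, Il1a was at −5.06, and without fl/fl 2 Il1a, Tnfsf10 and Csf1 were at −1.96, −1.68 and −1.80. For this list, 2 were lower when adjusted over the list alone, 3 over all genes without fl/fl 1, and 6 lower with 1 higher without fl/fl 2. Camera gave adjusted p = 0.00565 for the chemokines and 0.0264 for the cytokines, and for both adjusted p = 0.595 with an estimated correlation. The cytokine call ended without wt/wt 1 (adjusted p = 0.364), without fl/fl 2 (0.133) or with no filter on low counts (0.0557). None of 18 NF-kappaB targets and regulators passed in edgeR or when adjusted over the list alone, with 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom, at a median log2 fold change of −0.31 (camera adjusted p = 0.0727). Beside these differences, the precursor and neutrophil lists were at medians of 3.45 and 1.66 in the same libraries.

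Some glycolysis and hypoxia genes fell in fl/fl, and 1 oxidative phosphorylation gene rose. Vegfa, the angiogenic growth factor, held 719 and 502 CPM in wt/wt and 103 and 57.8 in fl/fl (log2 fold change −2.93 ± 0.33, SE; adjusted p = 0.0120, edgeR). The hypoxia-induced genes P4ha1 and Bnip3 (−1.99 and −2.35) and Hk2, a hexokinase of the first step of glycolysis (−1.63), fell as well. Of 24 genes in this list, 11 fell and 13 did not pass (15 lower when adjusted over the list alone). Their median was −0.96, or −1.37 without fl/fl 1 and −0.64 without fl/fl 2. Camera gave adjusted p = 2.43e-07, and adjusted p = 0.595 with an estimated correlation. Bnip3 shares 22.3% of its exonic length with a gene on the opposite strand, and the strand setting of the counting is not given in the sources used here. All 28 oxidative phosphorylation genes had a positive log2 fold change, with a median of 0.35. Ndufa4, a respiratory chain subunit, rose by 0.80 (adjusted p = 0.0307), and the other 27 did not pass, with Ndufb9, Ndufb5 and Cox6c at 1.01, 0.70 and 0.61 (5 higher when adjusted over the list alone). Its camera call (adjusted p = 1.77e-05) was likewise lost with the correlation estimated (adjusted p = 0.595 with an estimated correlation). The estimate of 0.00468 lay below the preset 0.01, so correlation between these genes does not explain the loss. In the same comparison the medians of the granulocyte precursor, neutrophil and cell cycle lists were 3.45, 1.66 and 2.78.

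Of 25 myeloid suppression and metastasis support genes, 5 rose and 7 fell (6 higher and 10 lower when adjusted over the list alone; 11 lower over all genes without fl/fl 1 and 8 higher without fl/fl 2). The neutrophil gene S100a9 (3.10) and Wfdc17 (1.72), a whey acidic protein family member, were among those higher, and Vegfa and the thrombospondin gene Thbs1 (−1.57) among those lower. The list did not pass camera (adjusted p = 0.486). Its median was 0.04, or −0.55 without fl/fl 1, and its mean was 0.18. Of 25 immediate early and dissociation genes, which respond within minutes to handling of cells, 3 fell and 1 rose (1 higher and 5 lower when adjusted over the list alone; 5 lower over all genes without fl/fl 1, and 7 in DESeq2). Egr2 (−1.19), Egr1 (−0.85) and the heat shock gene Hspa1b (−0.73) were lower and Klf2 higher (0.99); Hspa1b no longer passed without fl/fl 2 (adjusted p = 0.0743). Camera gave adjusted p = 0.0127 for the immediate early list, adjusted p = 0.595 with an estimated correlation, and 0.0620 and 0.108 without wt/wt 1 and fl/fl 1.

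**Figure D3:**
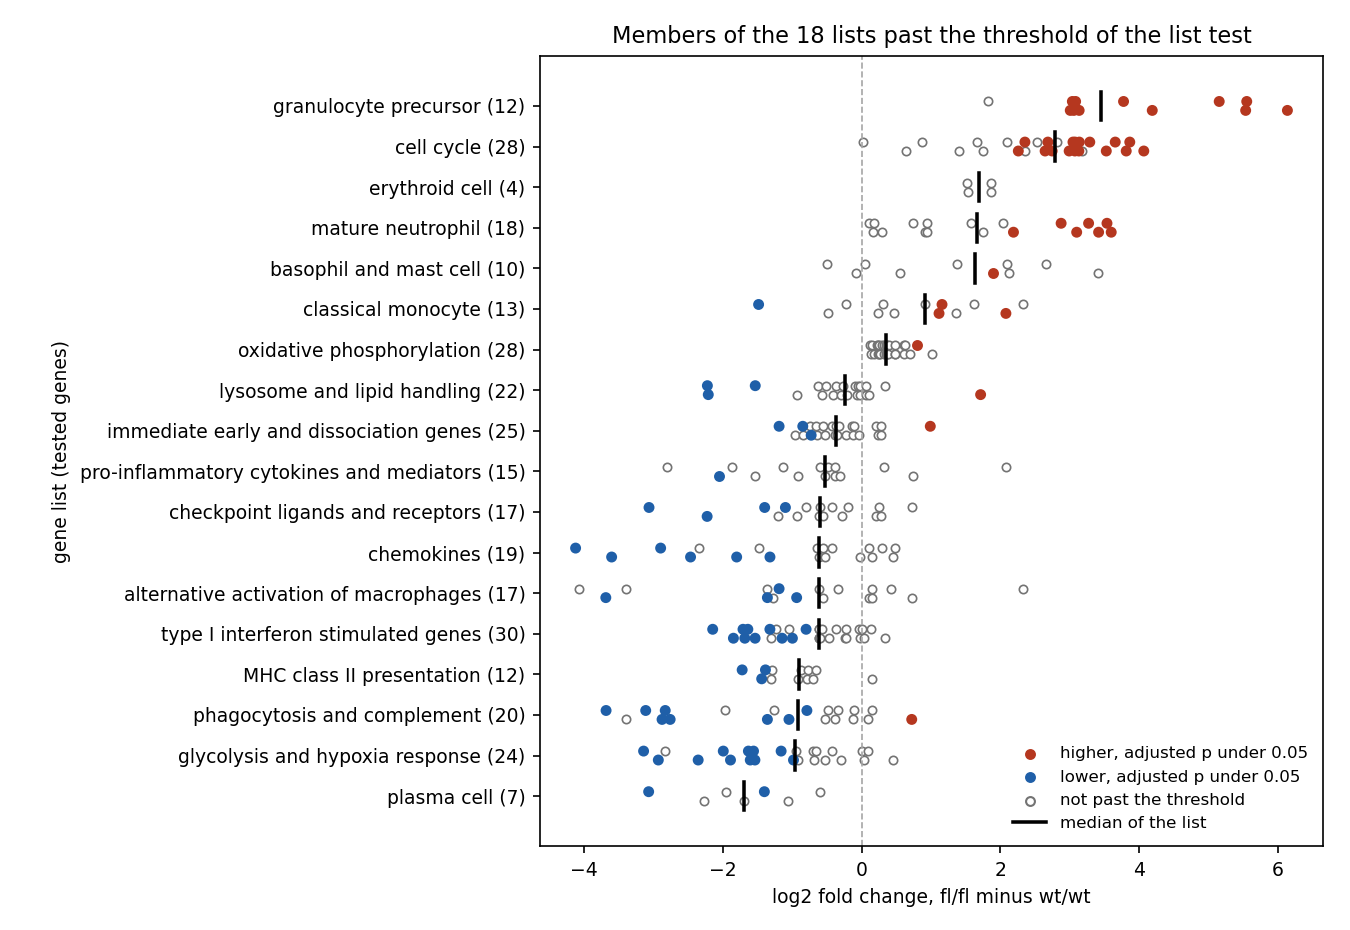
Log2 fold change of each tested member of the 18 lists that passed camera with a preset correlation, where filled points mark genes past the threshold in edgeR (red higher, blue lower), open points the others and black bars the medians. Medians range from 3.45 for granulocyte precursor genes to −1.69 for plasma cell genes; none of the 18 lists passed with an estimated correlation (adjusted p = 0.595).

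Markers of other cell types were examined in the same libraries. Of 7 plasma cell genes, Sdc1, the gene of syndecan-1 (−3.07), and the transcription factor gene Prdm1 (−1.40), which macrophages also express, fell (2 lower when adjusted over the list alone), while Igkc, Jchain and Igha were at −1.96, −1.69 and −1.06 without passing. Without fl/fl 1 these 3 genes were at −5.14, −4.52 and −9.06 (Igha from 2 counts in fl/fl 2). Without fl/fl 2 they were at −1.04, −0.79 and −0.06. Igkc held 30.1 and 37.1 CPM in wt/wt and 16.3 and 0.970 in fl/fl. The plasma cell list had a camera adjusted p = 0.0157, adjusted p = 0.595 with an estimated correlation, and 0.0630 and 0.154 without wt/wt 2 and fl/fl 2; 5 of its genes passed without fl/fl 1 and 3 without fl/fl 2, at list medians of −5.14 and −1.04. Of 14 NK cell and ILC1 genes, the cytotoxic granule genes Gzma (3.10), Nkg7 (3.67) and Prf1 (3.47) rose (4 higher and 2 lower when adjusted over the list alone; 3 higher and 2 lower over all genes without fl/fl 2), and Ccl5 and Itga1 were at −1.47 and −0.35 without passing. Ccl5 was at −0.90 without wt/wt 1 and −1.77 without fl/fl 2. Itga1 was at −0.08 and −0.73 without fl/fl 1 and fl/fl 2. The NK list had a mean of 0.54 and a median of −0.04, or 0.90 without wt/wt 1 and 0.08 without fl/fl 1, and it did not pass camera (adjusted p = 0.389). None of 22 hepatocyte genes passed in edgeR, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (camera adjusted p = 0.300). The albumin gene Alb held 40.0 and 26.7 CPM in wt/wt and 9.55 and 60.7 in fl/fl, and Trf, of which 63.5% of the exonic length is shared with another gene model, held 215, 350, 200 and 324 CPM; Ambp, Hpx, Cyp2e1 and Serpina1b were at 1.20, 0.89, 1.86 and 0.99. Alb was at 0.83 without fl/fl 1 and −1.79 without fl/fl 2, and Serpina1b at 1.56 and −0.10. The sign of both genes thus depended on which fl/fl library was kept. Cyp2e1 was at 0.38 without fl/fl 2. Of 15 nonclassical monocyte genes, Pglyrp1, a peptidoglycan-binding protein also made by neutrophils, rose (3.09; 1 higher when adjusted over the list alone; 3 genes passed over all genes without fl/fl 1 and also without fl/fl 2). Cx3cr1, the fractalkine receptor gene, was at −1.35 (adjusted p = 0.0934; −0.89 without fl/fl 1 and −2.12 without fl/fl 2), Spn, Cd300e, Nr4a1 and Itgal at 0.76, −2.09, 0.28 and 0.27 (Spn 0.46 without wt/wt 1; Cd300e −3.53 and Nr4a1 0.04 without fl/fl 2). The nonclassical list did not pass camera (adjusted p = 0.390); its median of 0.24 was −0.14 without fl/fl 2.

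The other fixed lists did not pass camera, and the genes named from them were chosen after their values were seen. Of 4 eosinophil genes, Prg2, a granule protein gene, had no counts in wt/wt and was at least 15.0-fold higher in fl/fl, from the 3 counts that a 0 allows per library (camera adjusted p = 0.133); it did not pass without fl/fl 2 (adjusted p = 0.104), and 3 eosinophil genes passed without fl/fl 1. Of 13 conventional dendritic cell genes, Itgax, which encodes CD11c, fell (−2.02; camera adjusted p = 0.0593; 2 passed without fl/fl 1 and 4 without fl/fl 2). Of 12 endothelial genes the inhibitory Fc receptor Fcgr2b fell (−0.79; camera adjusted p = 0.389; 2 genes passed without fl/fl 2), and the list of 5 epithelial genes had a camera adjusted p = 0.687. Of 5 platelet genes the coagulation factor gene F5 rose (1.07) and Pf4, platelet factor 4, fell (−2.30, not called by limma-voom; camera adjusted p = 0.877). Of 13 iron and heme genes, Hmox1 and the metal transporter gene Slc11a1 (−0.96) fell (camera adjusted p = 0.218), and of 19 neighbours of Il10ra on chromosome 9, Jaml, an adhesion molecule of leukocytes, rose (1.60; camera adjusted p = 0.0870; 2 passed without fl/fl 1 and without fl/fl 2). Adjusted over the list alone, the counts higher and lower were 1 and 0 for eosinophil, 0 and 1 for dendritic, 0 and 1 for endothelial, 1 and 1 for platelet, 0 and 2 for iron and 1 and 1 for the neighbours. None of 3 T cell, 6 B cell, 3 plasmacytoid dendritic cell, 6 stellate cell and fibroblast genes or 4 sex markers passed over all genes in edgeR (camera adjusted p = 0.127, 0.444, 0.0805, 0.134 and 0.120), and adjusted over the list alone 1 T cell gene was higher and 2 plasmacytoid and 2 stellate genes were lower. At an unadjusted p under 0.05 there were 1, 0, 2, 3 and 0 genes in these lists. DESeq2 called 1, 0, 1, 2 and 1 of their members and limma-voom 0. The 4 tested sex markers were the Y-linked genes, at a median log2 fold change of −1.53. Xist, with counts in fl/fl 2 only, was removed by the filter. That none passed therefore does not show that the libraries are alike in sex. By the Xist and Y-linked counts they were not, with fl/fl 2 female and the other libraries male.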

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

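The settings were planned, except DESeq2 on 3 libraries, the removal of the length trend and the neutrophil factor list without fixed list members, which were tests chosen only after the result was seen. The number of genes past the threshold, 790, was 2088 with no filter on low counts, where 22696 genes were tested, 1215 with the replicate number as a block (783 of them shared), 1507 in DESeq2 (789 shared) and 319 against a minimum fold change of 1.5. Between 0 and 1477 genes passed when each library was left out in turn; the 0 of edgeR without wt/wt 1 or wt/wt 2 had 1576 and 2333 genes at an unadjusted p under 0.05, and DESeq2 without them called 464 (399 shared) and 771 (546 shared). In those fits the spread comes from the fl/fl pair alone, and the biological coefficient of variation was 0.314 and 0.315, against 0.240 without a fl/fl library. Other scalings gave 772 to 1007 genes, the CPM filter 836 and limma-voom 665. The block has no pairing behind it: deviations of libraries with the same number correlated at 0.0215 across genes. Of the 18 lists, 0 passed with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.143. Of all 40 lists, 18 to 22 passed with single libraries left out and 19 on ranks; the cause was not tested. The Il10ra log2 fold change stayed negative in all settings, from −6.18 to −3.92 with single libraries left out, and Cd274 from −0.86 to −0.22. Under the block and limma-voom, the signs of Alb (−0.39, −0.42), Gata2 (−0.15, −0.17) and Pdcd1lg2 (−0.11, −0.58) turned, none of them past the threshold. With single libraries left out, the ranges that cross 0 were −1.79 to 0.83 for Alb, −1.02 to 0.61 for Gata2, −9.06 to 1.04 for Igha, −0.0136 to 0.48 for Itgal, −3.25 to 1.63 for Pdcd1lg2, −0.10 to 1.56 for Serpina1b, −0.25 to 0.15 for Socs3, −0.0434 to 0.0947 for Stat3 and −0.49 to 0.29 for Trf; the cause was not tested. With the length trend removed, the medians of the oxidative phosphorylation and glycolysis lists were 0.31 and −0.98. Depth limits the low genes: a library's 3 counts are 0.111 to 0.175 CPM.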

Other observations

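The 6 lists in these observations, the length trend and the tests on granulocyte, macrophage and undeleted-cell explanations were chosen only after the result was seen. The tests on carried-over RNA and on the unseen TGF-beta genes were set before their values were. Adjusted p-values of camera and fry for the 6 lists were adjusted over these 6 lists alone.

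Some TGF-beta signalling genes were lower in fl/fl. Tgfbr1, the type I receptor, held 201 and 171 CPM in wt/wt and 53.2 and 50.6 in fl/fl, and Smad7, a feedback inhibitor of the pathway, held 130 and 81.9 against 22.8 and 21.7 CPM. The repressors Ski and Skil had log2 fold changes of −1.63 and −2.13, and Ltbp3, which holds latent TGF-beta, of −4.06. Of 27 tested genes, 11 were lower and 16 did not pass in edgeR (20 lower when adjusted over the list alone), with a median of −0.93. With 8 members seen beforehand included, the list had a camera adjusted p = 7.65e-09, adjusted p = 0.13 with an estimated correlation and a fry adjusted p = 0.00532. These values are not independent support, and fry was not run without those members. A possible explanation is that the list rests on the 8 members seen among the leading genes before it was written. The other 19 genes still had an unadjusted camera p of 6.07e-05 (0.0488 with an estimated correlation), with 15 negative and 5 lower. These unadjusted values cannot be set against the adjusted ones of the whole list. Leaving out fl/fl 1 or fl/fl 2 gave 13 and 16 lower genes, and leaving out wt/wt 1 or wt/wt 2 gave 0 in edgeR, as for all genes, while DESeq2 on all libraries called 13. In the same libraries the granulocyte precursor list had a median of 3.45 and the phagocytosis and complement list of −0.92. Of 17 growth and angiogenic factors, 4 were lower (median −0.63, or −1.11 without fl/fl 2 and −1.0 without wt/wt 2). Camera gave adjusted p = 0.000359 for them, and adjusted p = 0.175 with an estimated correlation. That list was also written after the data were seen and was not tested without members seen beforehand. Its values are thus not independent support.

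Among an added list of transcription factors and granule genes of neutrophils, 9 of 21 rose (14 without fl/fl 2) and 1 fell (camera adjusted p = 1.14e-07, adjusted p = 0.430 with an estimated correlation). Cebpe, which drives secondary granule genes, rose by 3.01, and Myb, a factor of proliferating progenitors, by 2.76. Cebpe is also in the precursor list. Without it, in a test chosen after the data were seen, 8 of 20 rose (unadjusted camera p = 1.48e-07, or 0.219 with an estimated correlation). Cebpa, which acts early in granulocyte and monocyte development, fell (−0.71); it was at −0.75 without fl/fl 1 and −0.71 without fl/fl 2, where the adjusted p of 0.0628 and 0.0583 in edgeR did not pass. None of 85 cytosolic ribosomal protein genes passed in edgeR (7 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom), and 76 were positive, with a median of 0.18 (camera adjusted p = 0.000359, adjusted p = 0.699 with an estimated correlation). None of 13 mitochondrially encoded genes passed in edgeR (1 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom; median −0.18, camera adjusted p = 0.499), and of 20 integrins and adhesion receptors 2 rose and 5 fell (median 0.00, camera adjusted p = 0.600).

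Granulocyte precursor genes were higher in fl/fl, and higher in fl/fl 1 than in fl/fl 2. The rise did not rest on fl/fl 1 alone, since the list's median log2 fold change without it was 2.69. Its 95% bootstrap interval over genes was 2.41 to 3.62. This interval treats genes as independent, though their estimated correlation was 0.836. It does not measure the spread between libraries, with 1 fl/fl library in that fit. Nor did the rise rest on the scaling, since the lowest median over 3 other scalings was 3.42. A candidate explanation is a larger share of dividing granulocyte precursors in the sorted fraction, which the CD11b gate does not exclude: the precursor and cell cycle lists differed between fl/fl 1 and fl/fl 2 by medians of 1.61 and 1.54, a difference of 0.0700. The neutrophil list, at 1.09, also lay within the limit of 1 log2 unit, and the SD over all genes was 0.814, so this value does not decide for or against that share. Whether such a share would follow from the genotype, the individual mouse, tumour load or the sort was not tested, and 2 libraries per group do not separate these.

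Of the phagocytosis and complement genes, 8 of 20 were lower in fl/fl and granulocyte genes were higher, while the Kupffer cell list did not pass camera (adjusted p = 0.0651) and Adgre1 was at −0.24 (adjusted p = 0.406, edgeR). Dilution of every other cell type by granulocytes would lower other myeloid markers alike. The nonclassical monocyte list had a median of 0.24 against −0.92 for phagocytosis and complement, but −0.14 against −0.82 without fl/fl 2. There the gap of 0.682 had a bootstrap interval over genes of −0.178 to 2.12, so dilution stays open. That interval does not measure the spread between libraries. The nonclassical list also holds Pglyrp1, which neutrophils make as well, so it is not free of granulocyte genes as a measure of dilution. The fall did not come from fl/fl 2, the library with Xist counts, alone: without it 10 of 20 phagocytosis and complement genes were lower in edgeR, against 8 with all libraries. A loss of some macrophages and a lower expression per cell may both contribute, and bulk libraries do not separate them.

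Il10ra, which was taken as the floxed gene before the data were examined although the labels do not name the chain, kept reads in fl/fl, at 6.59% of the wt/wt mean in fl/fl 1 and 1.41% in fl/fl 2. Carry-over of wt/wt RNA or reads does not account for those in fl/fl 2, which had 1 Y-linked count where 58.8 were expected (exact Poisson upper bound 5.57). For fl/fl 1 carry-over stays open: 0 of 9160 genes lay below the 6.59% that Il10ra kept there, by an adjusted Poisson p under 0.05. In fl/fl 2, 28 genes lay below that same 6.59%, with Y-linked genes not left out. Among genes with at least 50 CPM in wt/wt, the lowest was Ltbp3 in fl/fl 1, at 7.0%, and the Y-linked Ddx3y in fl/fl 2, at 0%. Cells without deletion and exons outside a deleted part cannot be told apart from gene totals; the level of Il10ra in fl/fl 1 was 4.67 times that in fl/fl 2, and 3 of 20 phagocytosis and complement genes had a larger ratio. The median ratio of that list was 1.38 (range 0.313 to 17.9).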
